A study of Mus musculus with 6 samples.

How the data were processed

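Bulk RNA-seq of the inner curvature of the mouse aortic arch was analysed in 6 samples, 3 from animals given ABT263 and 3 from animals given vehicle. Per the labels' protocols, RNA was purified on RNeasy Micro columns and 100 to 200 ng per sample went into TruSeq RNA v2 libraries, a kit that does not mark the strand. Reads of a gene and of an antisense neighbour can therefore not be told apart. The samples were grouped by their treatment label, and the columns of the table were matched to samples by title. The replicate numbers used here are only names and pair no samples. The labels do not state whether each sample came from a separate animal, so the p-values measure the spread between these samples.

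The deposited values were raw counts per gene symbol, not normalized. Per the submitters' processing notes, TopHat2 2.0.14, Bowtie2 2.2.6 and featureCounts 1.4.6 from the Subread package were used, with the builds mm10 and GRCm38. The annotation release, the strand setting, the treatment of reads with several alignments and any filter were not given in the sources used here. This matters for genes with a near-identical copy or an overlapping neighbour: values of Hspa1a and Hspa1b, of C4b, of the adjacent genes C2 and Cfb, and of the class II H2 genes depend on how such reads were assigned, and are uncertain for that reason. The table held 24062 gene symbols, of which 5456 had no count in any sample. None of the 13 mitochondrially encoded genes on the fixed list was found in the table under its symbol, so they could not be analysed. Gene positions were taken from a RefSeq gene table of GRCm38.p6, the same build, in which 23902 of the symbols were found, 22550 of them under the same spelling. Positions are 1-based and span the whole gene, with all its exons and introns.

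Library totals ran from 12768501 to 21136555 counts. Pairs of libraries were compared for duplicates over genes with at least 10 counts, and the closest pair (ABT263 replicates 1 and 3) still differed far beyond sampling noise, with a chi-square of 18.9 per degree of freedom, so all 6 were kept as separate samples.

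Differential expression was tested with edgeR 4.0.16 in R 4.3.3: TMM normalization, the default expression filter by group, which left 14318 genes, and the two-sided quasi-likelihood F-test with robust empirical Bayes, followed by Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are ABT263 over vehicle on the log2 scale, given with the standard error or the 95% confidence interval, whose median half-width was 0.58. CPM values are counts scaled to the TMM-adjusted library total. Before the data were examined, 45 gene lists were fixed from textbook knowledge, covering the vessel wall, the BCL-2 family, senescence, stress responses, metabolism and the cell types that an aortic dissection can carry along, together with 27 focus genes. Lists with at least 3 tested members (43 of 45) were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the 43 lists. Each list was tested again with an estimated correlation and with fry, which asks whether the genes of a list move on balance one way. For each list, members were also counted after adjustment over the list alone. List means were compared by an exact permutation test, for which 3 samples against 3 allow no two-sided p below 0.1.

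The genes named are the focus genes, up to 4 members of each list with the smallest p, and up to 12 genes per direction that passed the threshold with a mean of at least 1 CPM and no overlap between the groups. Because none passed, the 12 per direction with the smallest p under the same filters are named as not having passed. Predicted genes and clone identifiers were skipped, which applied to 2 of those with lower values. Outside this rule, Rn45s, Ucp1, Myh6, Actc1, Cd8a, Cd74, Hspb1, C3, Ptprc, Stbd1, Saa3, the genes given as examples of DESeq2's calls and the thymic epithelial genes were picked after their values were seen.

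The procedure was tested on simulated counts with the real means and library totals, for ABT263 against vehicle. With the observed gene-wise dispersion (median biological coefficient of variation 0.264), 7 of 100 genes changed 2-fold and 55 of 100 changed 4-fold were recovered, with 3 false calls among 14130 genes tested. With a dispersion of 0.01, 99 and 100 of 100 were recovered with 8 false calls among 14218. In a simulation of lists with a fixed dispersion in place of the observed ones, all 10 lists shifted 1.5-fold and none of 40 unshifted lists were called. All simulated genes, also those of the gene test, were drawn independently of each other, unlike real co-regulated genes. These results therefore give no rate of false calls for the real lists.

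The alternatives comprised RLE and upper-quartile normalization and plain library totals, DESeq2 1.42.0, limma-voom with and without sample quality weights, the test without robust empirical Bayes, 3 other expression filters, a fold threshold of 1.5, an adjusted p of 0.1, the mean of the adipocyte or skeletal muscle list as a covariate, and leaving out each sample in turn. A cardiac muscle covariate and a run without the 2 libraries highest in brown adipocyte genes were added after seeing the data, as were 5 further gene lists.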

Results

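Gene expression was measured by RNA-seq in the inner curvature of the aortic arch, a site of disturbed flow where atherosclerotic lesions form early, from C57BL/6 mice lacking the low-density lipoprotein receptor (Ldlr-/-) and kept on a diet labelled LFD. Mice had been injected intraperitoneally 1 time a day for 7 days with 100 mg/kg ABT263 or with vehicle. ABT263 (navitoclax) inhibits anti-apoptotic members of the BCL-2 family and is used as a senolytic, a drug that kills senescent cells. Each group held 3 samples, and all means below are given with the SD over n = 3. The ABT263 libraries held 16798769, 12768501 and 18240782 counts and the vehicle libraries 16834114, 21136555 and 19343941 counts. Between 15795 and 17434 genes were detected per library. The smooth muscle actin gene Acta2 took the most counts in 5 libraries (0.839% to 1.95%), and the ribosomal RNA precursor Rn45s did so in ABT263 replicate 2 (1.33%, against 0.679% to 1.15% in the other 5).

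The targeted gene Ldlr (chromosome 9, 21723576 to 21749919 on GRCm38) was counted at 259 ± 126 CPM in ABT263 samples and 248 ± 24.0 CPM in vehicle samples, a log2 fold change of 0.06 with a 95% confidence interval from -0.90 to 1.03. All 6 samples carry the knockout and the counts cover the whole gene, so this value checks no label.

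The comparison asks how 7 days of ABT263 change the vessel wall of these mice. Large differences were seen in transcripts of T cells and their precursors, whose list means were lower in all 3 ABT263 samples than in any vehicle sample and uneven among the vehicle samples. Tcf7, a transcription factor of T cells and their precursors (chromosome 11, 52246527 to 52283383), had 2.05 ± 0.656 CPM with ABT263 and 66.5 ± 79.1 CPM with vehicle. Cd3d, a chain of the T cell receptor complex (chromosome 9, 44981769 to 44987052), had 0.187 ± 0.156 CPM against 8.74 ± 9.34 CPM. In the other direction, Crym, a thyroid hormone binding protein (chromosome 7, 120186380 to 120201989), had 8.27 ± 2.04 CPM against 2.26 ± 0.251 CPM, and complement factor B, Cfb (chromosome 17, 34856374 to 34862514), had 107 ± 10.2 CPM against 50.3 ± 10.3 CPM.

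None of these genes, nor any other of the 14318 tested, passed an adjusted p of 0.05 in edgeR's quasi-likelihood test. The smallest adjusted p was 0.999. At an unadjusted p under 0.05 there were 567 genes, 204 higher and 363 lower with ABT263, where chance alone would give 715.9. The excess of lower genes depended on the libraries and the scaling: plain library totals gave 98 higher and 520 lower, and the counts were 808 and 603 without ABT263 replicate 2, 203 and 182 without vehicle replicate 2, 159 and 192 without ABT263 replicate 3, 140 and 171 without vehicle replicate 1 and 134 and 586 without vehicle replicate 3. The CPM values of the groups did not overlap for 1328 genes, or 9.28%, and chance gives 10%. DESeq2 called 65 genes on the same counts, 13 higher and 52 lower, whereas limma-voom called 0 without and with sample quality weights (386 and 1451 genes at an unadjusted p under 0.05). DESeq2's calls included Tcf7 (-5.01), Lck (-4.48), Cd3d (-5.52), Cd8a (-5.37) and Cd19 (-3.78) on the lower side and Crym (1.88), Cfb, Slpi (1.74) and Fcna (1.88) on the higher side, all as DESeq2's log2 fold changes.

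Of the 12 genes with the smallest p on the lower side, none of which passed, several are genes of lymphocytes. Besides Tcf7 and Cd3d they were the T cell costimulatory receptor Cd27 (log2 fold change -4.79, SE 0.92), the T cell kinase Itk (-4.24, SE 0.91), the T cell adaptor Grap2 (-3.64, SE 0.65), the thymocyte chemokine receptor Ccr9 (-6.26), Nsg2 (-5.55), Zfp831 (-4.50), Tbc1d10c (-3.61), Rasal3 (-3.59), Traf3ip3 (-3.42) and Pag1 (-1.09, SE 0.19). Ccr9 rested on 4, 3 and 3 counts in the ABT263 libraries and on 766, 86 and 61 in the vehicle libraries. On the higher side, besides Crym and Cfb, stood the protease inhibitor Slpi (1.73, SE 0.35), the ficolin Fcna of the lectin complement pathway (1.88, SE 0.39), the endocytic receptor Lrp2 (0.73, SE 0.14), the Wnt agonist Rspo1 (0.78, SE 0.16), the tubulin Tubb6 (0.75), Spock2 (0.67), Gpm6a (0.59), Obsl1 (0.55), Mir22hg (0.51) and Medag (0.49, SE 0.10). These also did not pass.

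Among the 43 lists tested, camera with its preset correlation called 5 lower and 12 higher with ABT263. None of the 17 calls held with an estimated correlation (smallest adjusted p = 0.591 with an estimated correlation) or with fry (smallest adjusted p = 0.347).

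The T and NK cell list was lower, with all 14 tested members negative and a median log2 fold change of -3.42 (camera, adjusted p = 4.84e-17; adjusted p = 0.591 with an estimated correlation). No member passed over all genes, but 13 passed adjusted over the list alone, among them the kinase Lck (-4.48; 1.69 ± 0.829 CPM with ABT263 and 38.0 ± 41.6 CPM with vehicle), the coreceptor Cd8a (-5.34) and Themis (-5.77), a regulator of thymocyte selection. That count became 0 without ABT263 replicate 1, 6 without ABT263 replicate 3 and 5 without vehicle replicate 1. The mean of the list was -0.72, -0.12 and 0.05 log2 CPM in the ABT263 libraries and 4.46, 2.90 and 1.39 in the vehicle libraries.

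B cell genes were lower in the same direction, with 13 of 13 members negative and a median of -3.42 (adjusted p = 4.28e-09; adjusted p = 0.634 with an estimated correlation). Examples were the coreceptors Cd19 (-3.79, 95% interval -6.78 to -0.80) and Cd22 (-3.42), the low-affinity IgE receptor Fcer2a (-4.02) and the adaptor Bank1 (-2.30). The receptor chain Cd79a had 2.77 ± 3.20 CPM with ABT263 and 30.1 ± 33.0 CPM with vehicle (-3.43, interval -6.96 to 0.10), and Cd3e of the T cell receptor 1.27 ± 0.993 and 8.69 ± 7.70 CPM (-2.79, interval -5.11 to -0.46). No B cell gene passed adjusted over the list alone, while without vehicle replicate 3 all 13 did. Without vehicle replicate 2, which had the highest B cell list mean (4.90 log2 CPM), the median was -1.86. The B cell list means of the groups overlapped, since ABT263 replicate 3 (1.52) lay above vehicle replicate 3 (0.87).

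The thymus and lymphoid organ list was also lower, with 8 of 8 members negative and a median of -2.17 (adjusted p = 3.37e-04; adjusted p = 0.591 with an estimated correlation). Its leading members act in immature lymphocytes: Rag1, which cuts antigen receptor genes, had 0.548, 0 and 0.701 CPM in the ABT263 libraries and 212, 12.2 and 12.99 CPM in the vehicle libraries. Dntt, which adds nucleotides at the junctions of those genes, had a log2 fold change of -7.07, and Arpp21 one of -4.40. Adjusted over the list alone, 3 of the 8 passed. None did without ABT263 replicate 1, 2 or 3, and 5 did without vehicle replicate 3. The median moved to -4.29 without ABT263 replicate 3, -1.26 without vehicle replicate 1, -1.38 without vehicle replicate 2 and -3.94 without vehicle replicate 3. The call was lost in limma-voom with sample quality weights.

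Genes of class II antigen presentation were lower in 9 of 9 members, with a median of -1.33 (adjusted p = 1.08e-07; adjusted p = 0.634 with an estimated correlation). H2-Ab1 had 68.6 ± 11.8 CPM with ABT263 and 173 ± 104 CPM with vehicle, the invariant chain Cd74 had 217 ± 32.7 and 518 ± 330 CPM, H2-Aa had a log2 fold change of -1.34, and H2-Ob, a modulator of peptide loading found mainly in B cells, one of -3.71. Adjusted over the list alone 5 members passed, none without any single ABT263 library or without vehicle replicate 2, and 9 without vehicle replicate 3. The median was -0.70 without vehicle replicate 2, the library richest in B cell genes.

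**Figure D1:**
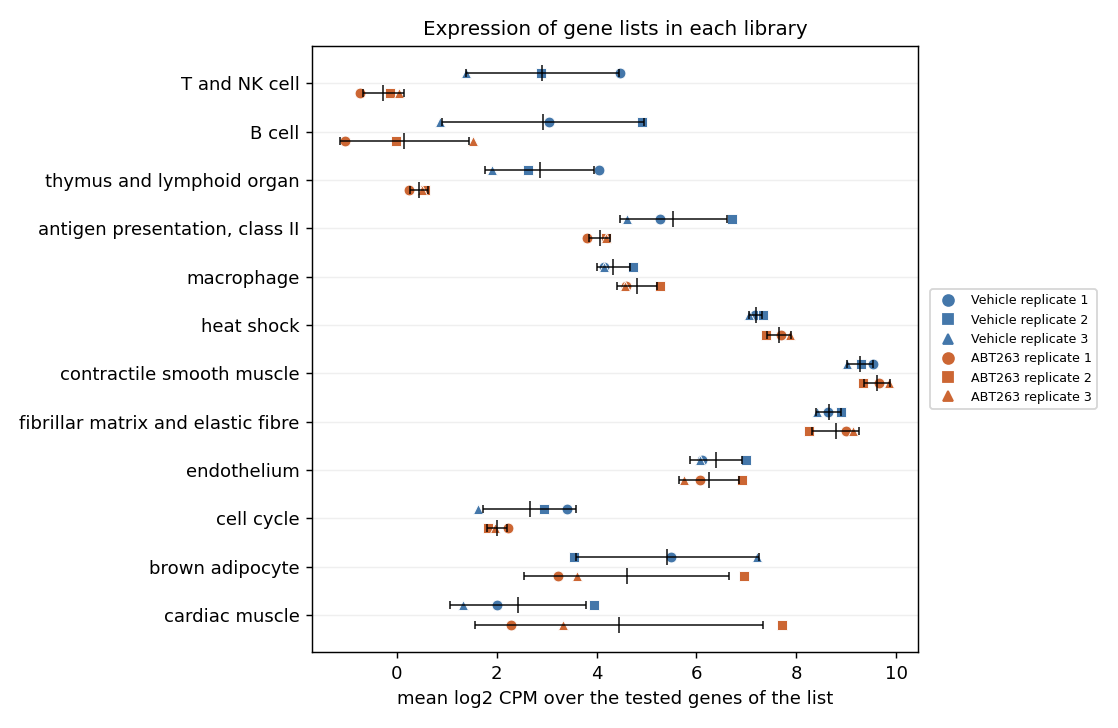
Mean log2 CPM over the tested genes of 12 lists in each library; points are single libraries, the bar is the group mean and the whiskers are ± 1 SD (n = 3). The 3 ABT263 libraries lie below all 3 vehicle libraries for T and NK cell, thymus and lymphoid organ and class II genes, and brown adipocyte genes range from 3.23 to 7.21 across the libraries of both groups.

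The cell cycle list was lower in 24 of 25 members, with a median of -0.89 (adjusted p = 3.77e-04; adjusted p = 0.842 with an estimated correlation), Mki67 at -1.70 and Ccnb1 at -1.67 being its leading members. Its mean was highest in vehicle replicate 1 (3.40 log2 CPM), the library with the highest Rag1 level. The call was lost without vehicle replicate 1 (adjusted p = 0.170, median -0.32) and without ABT263 replicate 2 (adjusted p = 0.0604, median -0.46), and with a filter of a mean of at least 10 CPM.

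Heat shock genes were higher in 10 of 12 members, with a median of 0.47 (adjusted p = 4.83e-06; adjusted p = 0.591 with an estimated correlation). The constitutive chaperone Hspa8 had 1992 ± 396 CPM with ABT263 and 1342 ± 162 CPM with vehicle, the small heat shock protein Cryab 224 ± 25.2 and 142 ± 32.2 CPM, and the inducible Hspa1a and Hspb1 had log2 fold changes of 1.02 and 0.78. No member passed adjusted over the list alone with all libraries, whereas 9 did without ABT263 replicate 2. The call held without each single library. The list means of the groups did not overlap (7.69, 7.39 and 7.87 log2 CPM against 7.17, 7.32 and 7.05; exact permutation p = 0.1, the smallest possible here). The T and NK cell, thymus and lymphoid organ and class II lists were separated in the same way, so that 4 of the 43 lists showed no overlap, about as many as the 10% that chance gives. Adjusted over the 43 lists, the exact permutation p of these 4 was 0.944.

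Macrophage genes had positive values in 13 of 17 members, with a median of 0.48, and the list was called higher (adjusted p = 4.76e-06; adjusted p = 0.780 with an estimated correlation). Cd5l (1.65), F13a1 (0.84), Cd68 (0.86) and Trem2 (0.87) led it, none past the threshold. Without ABT263 replicate 2 the call was lost (adjusted p = 0.0604, median 0.24), as it was with the cardiac muscle covariate and without the 2 libraries highest in brown adipocyte genes (0.173, median 0.16). Interferon-stimulated genes were likewise called higher (15 of 19 positive, median 0.35, adjusted p = 3.77e-04; adjusted p = 0.780 with an estimated correlation), with Ifit1 at 0.83 and Isg15 at 0.90. The median was 0.20 without ABT263 replicate 2 (adjusted p = 0.173), 0.60 without vehicle replicate 2 and 0.12 without the 2 libraries (0.337). The interferon call was also lost with the cardiac muscle covariate and with a filter of a mean of at least 10 CPM.

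Genes of cholesterol synthesis and its regulation were called higher (15 of 19 positive, median 0.24, adjusted p = 0.00201, and 0.591 with an estimated correlation). This list was fixed under the name cholesterol synthesis and uptake, but it holds no uptake receptor. The farnesyl diphosphate synthase gene Fdps had 50.1 ± 8.77 CPM with ABT263 and 29.1 ± 5.66 CPM with vehicle, and Sqle a log2 fold change of 0.71. The median was 0.13 without vehicle replicate 2, where the call was lost (adjusted p = 0.0964), and 0.37 without vehicle replicate 3. The unfolded protein and integrated stress response list was called higher with a median of only 0.11 (12 of 17 positive, adjusted p = 0.00505; adjusted p = 0.591 with an estimated correlation). Its leading members Manf (0.56), Creld2 (0.55) and Hspa5 (0.46) belong to the endoplasmic reticulum. This call was lost without ABT263 replicate 2 (adjusted p = 0.104, median 0.19) and without vehicle replicate 1 (adjusted p = 0.0549), as well as with the cardiac muscle covariate and without the 2 libraries highest in brown adipocyte genes (0.156), and the median was 0.19 without ABT263 replicate 3 and 0.21 without vehicle replicate 2.

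Contractile smooth muscle genes had positive values in 19 of 20 members, with a median of 0.32 (adjusted p = 0.0260; adjusted p = 0.842 with an estimated correlation). Acta2 had 14939 ± 6641 CPM with ABT263 and 11396 ± 3272 CPM with vehicle, Tagln a log2 fold change of 0.37 (95% interval -0.53 to 1.27) and Myh11 one of 0.04 (-0.80 to 0.88). The members with the smallest p, Casq2 (4.07) and Pln (2.96), encode calcium handling proteins that heart muscle also expresses. Both values rested on ABT263 replicate 2 (Casq2 137 CPM against 2.03 to 5.20 in the other 5 libraries, Pln 491 against 12.8 to 30.0) and were 0.64 and -0.09 without it. The call was lost without ABT263 replicate 1 (adjusted p = 0.229, median 0.21), ABT263 replicate 3 (0.726, median 0.01), vehicle replicate 2 (0.0702) or vehicle replicate 3 (0.330, median 0.21) and with the adipocyte covariate, and the median was 0.53 without ABT263 replicate 2 and 0.49 without vehicle replicate 1. The fibrillar matrix and elastic fibre list had 25 of 28 members positive with a median of 0.14 (adjusted p = 0.0330; adjusted p = 0.885 with an estimated correlation). Elastin, Eln, had 6677 ± 2659 CPM against 4089 ± 1077 CPM, Col1a1 a log2 fold change of 0.08 and Col3a1 one of 0.23. Its call was lost without ABT263 replicate 1 (adjusted p = 0.559), ABT263 replicate 3 (0.813), vehicle replicate 1 (0.0576) or vehicle replicate 3 (0.494), with medians of 0.03, -0.0025, 0.15 and 0.08, and also with the adipocyte covariate and with a filter of a mean of at least 10 CPM. The median was 0.40 without ABT263 replicate 2 and 0.24 without vehicle replicate 2.

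The remaining lists called higher hold markers of cells outside the vessel wall or shifts close to 0. Cardiac muscle genes had a median of 3.55 (12 of 13 positive, adjusted p = 2.27e-04; adjusted p = 0.842 with an estimated correlation). This value rested on ABT263 replicate 2. In it the cardiac myosin gene Myh6 had 3820 CPM against 3.77 to 170 CPM in the other 5 libraries. The median was 0.06 without that library (adjusted p = 0.430). The call was also lost without vehicle replicate 3 (adjusted p = 0.0508) and in limma-voom with sample quality weights, and the median was 5.41 without vehicle replicate 2 and -0.48 without the 2 libraries highest in brown adipocyte genes (adjusted p = 0.814). Erythroid genes had a median of 1.15 (adjusted p = 0.0410; adjusted p = 0.842 with an estimated correlation) and -0.18 without ABT263 replicate 3, and their call was lost without ABT263 replicate 2 (adjusted p = 0.243), ABT263 replicate 3 (0.876), vehicle replicate 1 (0.0555), vehicle replicate 2 (0.0702) or vehicle replicate 3 (0.168). RLE scaling, sample quality weights, the 10 CPM filter, the adipocyte and cardiac muscle covariates and leaving out the 2 libraries highest in brown adipocyte genes ended it too. Neutrophil genes had a median of 0.90 (adjusted p = 0.0497; adjusted p = 0.842 with an estimated correlation), and that call was lost without ABT263 replicate 2, ABT263 replicate 3 or vehicle replicate 3 (adjusted p = 0.204, 0.286 and 0.351, medians 0.33, 1.15 and 0.58). It was also lost with RLE or upper quartile scaling, with sample quality weights, without a filter, and with the adipocyte or cardiac muscle covariate. The median turned to -0.06 without the 2 libraries highest in brown adipocyte genes (adjusted p = 0.919), and was 1.35 without vehicle replicate 2. Airway epithelium and mesothelium genes had a median of 0.43 (9 of 10 positive, adjusted p = 5.35e-04; adjusted p = 0.634 with an estimated correlation), led by the mesothelial gene Lrrn4 (0.48) and the keratins Krt19 (0.50) and Krt8 (0.58). The only negative member was the airway secretory gene Scgb1a1 (-1.37), so the list does not show airway epithelium as a whole to be higher. The call was lost without vehicle replicate 3 (adjusted p = 0.325) and without the 2 libraries highest in brown adipocyte genes (0.173), and the median was 0.26 without ABT263 replicate 3. Cytosolic ribosomal protein genes had a median of 0.07 (adjusted p = 0.0260; adjusted p = 0.885 with an estimated correlation), which became -0.01 with plain library totals. That call was lost without ABT263 replicate 3, vehicle replicate 2 or vehicle replicate 3 (adjusted p = 0.726, 0.0629 and 0.325). It was also lost with plain library totals, sample quality weights, the 10 CPM filter, the adipocyte or cardiac muscle covariate and without the 2 libraries highest in brown adipocyte genes (0.206). The median was -0.01 without ABT263 replicate 3, where 16 of 28 members were negative, 0.03 without vehicle replicate 3, 0.11 without ABT263 replicate 2 and 0.14 without vehicle replicate 1.

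The libraries also differed within groups in the tissue they held. Brown adipocyte list means were 3.23, 6.96 and 3.62 log2 CPM in the ABT263 libraries and 5.49, 3.55 and 7.21 in the vehicle libraries, and the uncoupling protein gene Ucp1 ran from 38.7 CPM in ABT263 replicate 1 to 2170 CPM in vehicle replicate 3. In the main test the adipocyte list gave no call (median -0.25, camera adjusted p = 0.702), and neither did the brown adipocyte list (median -0.48, adjusted p = 0.275). On all 6 libraries, the brown adipocyte list was called lower with the adipocyte covariate. With sample quality weights, also on all 6 libraries, both lists were called lower. Both were called lower without ABT263 replicate 2 (medians -2.54 and -2.97, adjusted p = 0.0101 and 0.00406) and without vehicle replicate 2 (-0.77 and -0.999, adjusted p = 5.17e-04 and 0.00101). The adipocyte median was -0.41 without vehicle replicate 1. The medians of both turned to 1.11 and 0.79 without vehicle replicate 3, 0.19 and 0.03 without ABT263 replicate 1, and 0.19 and 0.02 without ABT263 replicate 3. The first principal component, 44.2% of the variance, set ABT263 replicate 2 (76.4) and vehicle replicate 3 (37.7) apart from the other 4 (-38.1 to -10.3). Without these 2 libraries, a run chosen after seeing the data that left 2 samples per group, 47 genes passed, 3 higher (Stbd1, C3 and Hspa1a) and 44 lower, led by the pan-leukocyte phosphatase gene Ptprc (-2.64, edgeR adjusted p = 0.0122). Of these 47, 10 were also among DESeq2's 65 with all 6 libraries. The run left out vehicle replicate 3, the vehicle library with the lowest T and NK cell and B cell list means.

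The BCL-2 family, which holds the targets of ABT263 among other members, and the markers of senescence gave no call in the main test. In the BCL-2 family list, 6 of 16 members were positive and 10 negative (median -0.11, adjusted p = 0.943; medians -0.03 without ABT263 replicate 2, 0.03 without vehicle replicate 2 and -0.33 without vehicle replicate 3, where the adjusted p was 0.145). The pro-survival genes had log2 fold changes of -0.33 for Bcl2 (95% interval -0.95 to 0.29), 0.21 for Bcl2l1 (-0.43 to 0.85), 0.06 for Bcl2l2 (-0.22 to 0.35) and -0.06 for Mcl1 (-0.41 to 0.30). The list of senescence and secretory factors had 14 of 22 positive members and a median of 0.19 (adjusted p = 0.0703). It was called higher in 5 of 22 alternatives: plain library totals, no filter, a filter of 1 CPM in 3 samples, the skeletal muscle covariate and without vehicle replicate 2 (adjusted p = 0.00101, median 0.32). The median was 0.03 without vehicle replicate 3 (adjusted p = 0.829) and 0.12 without ABT263 replicate 2. Its cell cycle inhibitor Cdkn2a was near the detection limit, with 0.845 ± 0.206 CPM with ABT263 and 0.540 ± 0.340 CPM with vehicle, and Cdkn1a had 105 ± 26.4 and 88.0 ± 4.81 CPM. The chemokine gene Ccl8 (1.73) and the matrix protease gene Mmp3 (chromosome 9, 7445822 to 7455975; 36.1 ± 6.08 against 25.7 ± 2.78 CPM) had non-overlapping, higher values with ABT263, and Mmp12 (0.25) and Mmp13 (-0.05) overlapping ones. None of these passed. Il6 had no count in any library and Il1a at most 14 counts, so neither was tested.

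The IGF axis showed no detectable difference (5 of 15 positive, median -0.05, adjusted p = 0.824; with single libraries left out, medians of -0.13, 0.01 and -0.07 without ABT263 replicates 1, 2 and 3 and of -0.10, 0.05 and 0.00 without vehicle replicates 1, 2 and 3). Igfbp3, which binds and sequesters insulin-like growth factors (chromosome 11, 7206086 to 7215498), had 43.0 ± 2.82 CPM with ABT263 and 44.5 ± 14.4 CPM with vehicle, with an interval from -0.66 to 0.55. Igf1 had a log2 fold change of -0.04 (-0.65 to 0.57). Modulated smooth muscle genes had a median of 0.17 (12 of 17 positive, adjusted p = 0.0653), with Lgals3 (chromosome 14, 47373860 to 47386167) at 46.6 ± 4.48 CPM against 30.6 ± 6.97 CPM, without overlap but not past the threshold, and Spp1 at 0.17 (-1.66 to 1.99). This list was called higher in 9 of 22 alternatives, among them without ABT263 replicate 2 (adjusted p = 0.00227, median 0.37) and without vehicle replicate 2 (adjusted p = 3.83e-04). Its median was -0.01 without ABT263 replicate 1, 0.28 without ABT263 replicate 3 and 0.00 without vehicle replicate 3. Endothelial genes (median -0.12, camera adjusted p = 0.649, Pecam1 0.02) and platelet genes (median 0.19, adjusted p = 0.238, Pf4 0.19) gave no call in the main test. Neither did p53 targets (median -0.04, adjusted p = 0.953). The p53 median was -0.14 without ABT263 replicate 1, 0.10 without vehicle replicate 2 and -0.06 without vehicle replicate 3. The endothelial list was called lower without ABT263 replicate 2 (adjusted p = 0.00845, median -0.48), with the cardiac muscle covariate (1.77e-05) and without the 2 libraries highest in brown adipocyte genes (0.00170). Its median was -0.0014 without ABT263 replicate 1, 0.10 without ABT263 replicate 3, -0.21 without vehicle replicate 1, 0.35 without vehicle replicate 2 and -0.29 without vehicle replicate 3. The platelet list was called higher without ABT263 replicate 1 (adjusted p = 0.0225, median 0.32), without vehicle replicate 2 (0.00443, median 0.41) and with the skeletal muscle covariate, and its median was -0.23 without ABT263 replicate 2, 0.12 without vehicle replicate 1 and -0.0007 without vehicle replicate 3.

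**Figure D2:**
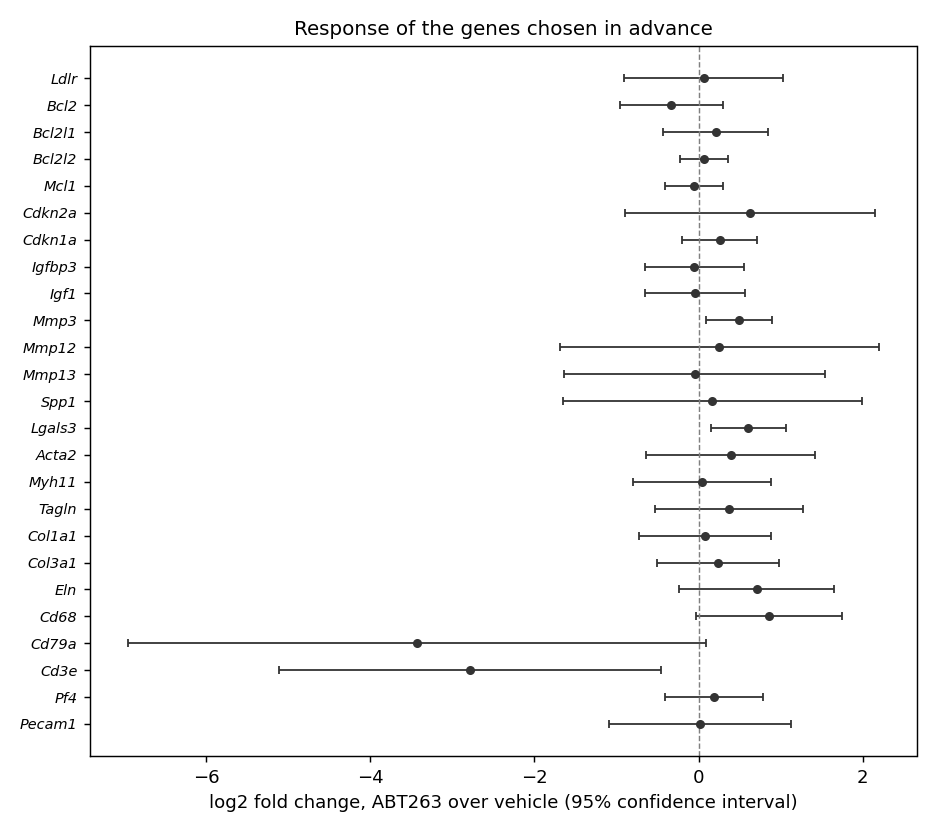
Log2 fold change, ABT263 over vehicle, of the 25 focus genes that were tested; points are edgeR estimates and bars 95% confidence intervals (n = 3 per group). The intervals of Mmp3, Lgals3 and Cd3e exclude 0 before adjustment, and no gene passed after it.

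**Figure D3:**
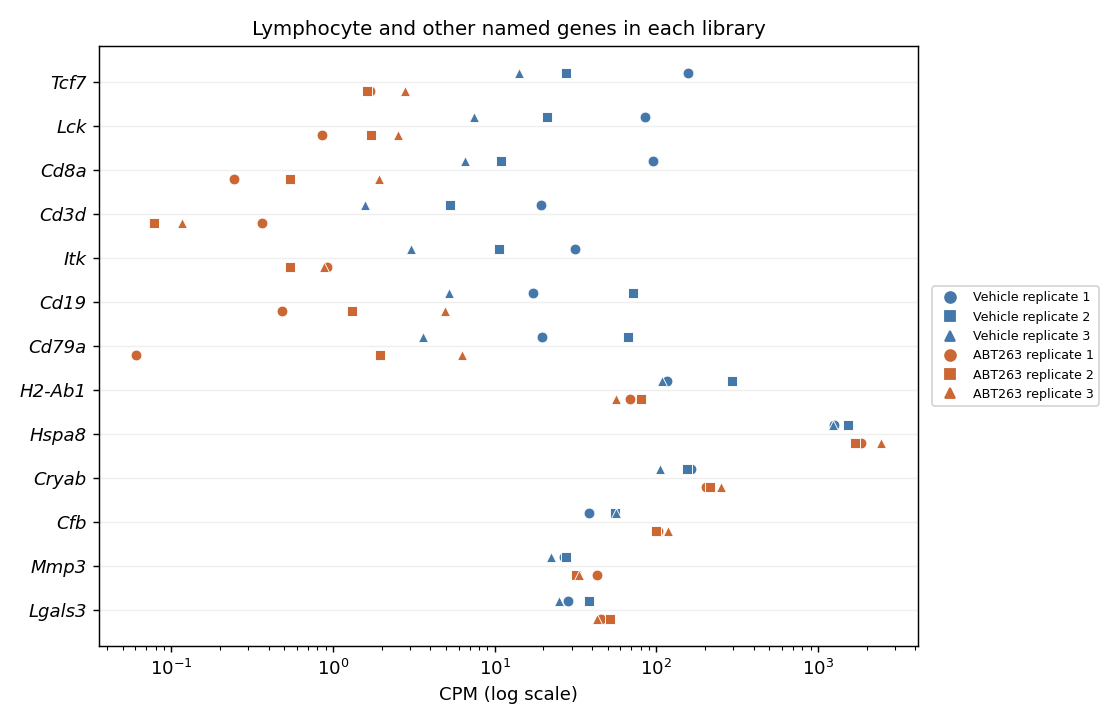
CPM of 13 named genes in each library on a log scale; each point is 1 library, blue for vehicle and orange for ABT263. The lymphocyte genes at the top are spread over a wide range among the vehicle libraries (Tcf7 14.1 to 157 CPM), while Hspa8, Cryab, Cfb, Mmp3 and Lgals3 at the bottom lie higher in all 3 ABT263 libraries.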

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

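The run without the 2 libraries highest in brown adipocyte genes and the cardiac muscle covariate were chosen after seeing the data. The count of genes past the threshold was 0 in the edgeR and limma-voom runs with all 6 samples, and moved to 65 with DESeq2 and to 47 without the 2 libraries; the cause of the difference between the tools was not tested. Leaving out single samples gave 0 to 0 genes, with a smallest adjusted p of 0.0530 without vehicle replicate 3. Of 43 lists, 17 were called; the count moved to 11 with a filter of a mean of at least 10 CPM, which left 40 lists to test, to 0 with an estimated correlation and to 0 with fry. Leaving out single samples gave 13 to 21 lists, and the other settings 12 to 22. The T and NK cell, B cell, class II and heat shock lists were called in the same direction in 20 of 22 alternatives, all but the estimated correlation and fry. Over the alternatives of 211 named genes, 4205 of 4352 values kept their direction and side of the threshold, 29 passed the threshold in the same direction, and 118 changed sign with no call. No called value of a named gene reversed. Among the lists, nuclear oxidative phosphorylation was not called in the main test but went both ways in the alternatives. Camera called it lower in 3 of them. These were all 6 samples with sample quality weights, the run without ABT263 replicate 2 (adjusted p = 0.00699) and the run without vehicle replicate 2 (0.00128). Without vehicle replicate 3 it was called higher (0.00400). Restricting the library totals to genes outside the erythroid, mitochondrial and B cell lists moved nothing and is void, as TMM rescales for it. Lists have no value without robust empirical Bayes, which camera does not use, and for DESeq2 they were tested on variance-stabilized values. No paired analysis was possible because the replicate numbers are only names. Depth limits rare transcripts such as Il1a and Cdkn2a, and plain library totals lowered the median of all genes from -0.01 to -0.08.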

Other observations

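The complement, tissue-resident macrophage and thymocyte lists, and the tests below of a general loss of leukocytes, of a common source of lymphoid cells and of myocardium, were chosen after the results were seen. Complement genes had positive values in 13 of 14 members, with a median log2 fold change of 0.49. Cfb passed adjusted over the list alone (edgeR adjusted p = 0.0106), but the list was written because Cfb and Fcna had been seen and is not independent evidence. The number that passed was 4 without ABT263 replicate 2, 0 without ABT263 replicate 3, and 3 without vehicle replicate 2 or 3. C4b had 323 ± 68.5 CPM with ABT263 and 167 ± 57.4 CPM with vehicle, C3 2435 ± 293 and 1294 ± 692 CPM, and C2 81.3 ± 10.8 and 52.2 ± 8.44 CPM (SD, n = 3). All 9 tissue-resident macrophage genes were positive (median 0.61), among them the complement receptor Vsig4 (2.37), the folate receptor Folr2 (0.95) and Lyve1 (1.08), and none passed adjusted over the list alone, whereas 3 did without ABT263 replicate 1. The median of that list was 0.38 without ABT263 replicate 2, with 8 of 9 positive. The means of both lists were separated between the groups, which in an exact permutation test gives p = 0.1, the smallest possible with 3 samples against 3. Of the genes on these lists, 4 of 15 complement, 6 of 9 tissue-resident macrophage and 7 of 8 thymocyte genes also stand on lists fixed beforehand. In DESeq2 the acute phase gene Saa3 was also called higher (log2 fold change 5.17). It had not passed the expression filter of the main test, so edgeR gave no value for it.

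The T and NK cell, B cell and thymus lists were called lower with ABT263 by camera with its preset correlation. None of these calls held with an estimated correlation (adjusted p = 0.591, 0.634 and 0.591) or with fry, and the B cell list means of the groups overlapped. The thymocyte genes (6 of 6 tested negative, median -6.01, and -3.70 without vehicle replicate 1) summed to 29, 18 and 52 counts in the ABT263 libraries and to 7890, 732 and 533 counts in the vehicle libraries. A loss of macrophages like that of the lymphocyte genes is argued against by the macrophage list, whose mean was 0.469 log2 CPM higher with ABT263 (SE 0.299). Its means overlapped between the groups (exact permutation p = 0.3), and its median fell to 0.24 without ABT263 replicate 2. The macrophage list cannot speak for leukocytes of every kind. Mast cell genes were negative in 6 of 7 tested members and neutrophil genes positive in 5 of 6. Whether the lymphoid transcripts had a common source stays open: the ratio of T to B cell genes spanned 3.42 log2 units over the 3 vehicle libraries, but how far it varies between samples of 1 tissue was not measured. Thymus carried along with the vehicle samples stays open as an explanation for the group. Thymic epithelial genes summed to 132 counts in vehicle replicate 1 (Tbata 60, Prss16 24, Psmb11 19) against 15 to 44 in the other 5 libraries. The log2 ratio of their summed CPM over the groups, -1.06 (SE 0.714), decides neither way. Ccl25 weighs on that ratio, with 33, 11 and 10 counts in the ABT263 libraries and 24, 33 and 37 in the vehicle libraries. Lymph node stroma and follicle genes, a list added after the 45 were fixed, were negative in 3 of 3 tested members. Their log2 fold changes ran from -3.38 to -0.07. The lowest was that of Cr2, which also stands on the B cell list, and 4 of the 6 genes stand on fixed lists. The list is therefore not separate evidence, and its means overlapped between the groups (exact permutation p = 0.3). An effect of the drug on lymphocytes and their precursors, which rely on BCL-2 family proteins for survival, is the biological hypothesis and cannot be told apart from thymus and lymphoid tissue in the vehicle dissections, because all 3 vehicle libraries hold thymocyte transcripts and only 1 holds clear epithelial ones.

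No gene passed the threshold, and carry-over of perivascular fat is a candidate explanation. With the adipocyte list mean as a covariate the biological coefficient of variation fell from 0.363 to 0.258, but 0 genes passed (smallest adjusted p 0.437). That result lies between the bounds set beforehand for and against the explanation, which stays open. The coefficient was 0.214 and 47 genes passed without the 2 libraries highest in brown adipocyte genes. That run was chosen after seeing the data and also removed the library highest in cardiac muscle genes. It removed vehicle replicate 3 too, the vehicle library with the lowest T and NK cell (1.39 log2 CPM) and B cell (0.87) list means. The run therefore cannot separate fat from the lymphocyte content of the vehicle libraries. Leaving out vehicle replicate 3 alone gave a smallest edgeR adjusted p of 0.0530, and ABT263 replicate 2 alone 0.507, with 0 genes passed in each. Over the other splits of the 6 samples into 3 and 3, edgeR gave 68 to 2426 genes at an unadjusted p under 0.05, against 567 for the treatment. The highest count came from ABT263 replicate 2, vehicle replicate 3 and vehicle replicate 1 against the other 3 libraries. The treatment was therefore not the split with the most such genes, although some other splits gave fewer. The 6 samples allow 10 splits, too few for a share under 0.05. For genes the count of splits is void, since the real split called 0 and every split gives at least that (highest other 0). For lists, 5 of 10 splits gave as many (17 in the real split, highest other 21).

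The cardiac muscle list was called higher with ABT263 by camera with its preset correlation, but not with an estimated one (adjusted p = 0.842). Its means overlapped between the groups, with 2.30, 7.72 and 3.33 log2 CPM against 2.01, 3.95 and 1.33 (exact permutation p = 0.4). Myocardium in ABT263 replicate 2 may be the source of the high value. Without that library the median of the list was 0.0641, against 3.55 with it, and Myh6 (3820 CPM) and Actc1 (1326 CPM) were abundant in it. That the drug acts on cardiac genes has no further test in this design.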
